A study of Mus musculus with 4 samples.

How the data were processed

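Single-cell RNA sequencing of spinal cord was analysed in 4 libraries from aged C57BL/6J mice, an inbred laboratory strain. The tissue came from the lesion segment 28 days after spinal cord injury, from mice given either an IgG antibody or an antibody against CD8, the co-receptor of cytotoxic T cells, with 2 libraries in each of the 2 groups. Per the labels' protocols, mice were perfused with artificial cerebrospinal fluid, the tissue was dissociated with an enzymatic kit, myelin was removed with beads and cells went into droplet-based 3′ sequencing with unique molecular identifiers (UMIs). The series design calls the libraries of a group biological replicates and does not say how many mice went into a library, so p-values measure the spread between these libraries.

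The deposited values were raw UMI counts per gene and cell barcode, as whole numbers, with no normalisation. They were made with Cell Ranger 7.1.0 on genome build GRCm39, per the submitters' processing notes; the annotation release and the treatment of intronic reads are not given in the sources used here. The count tables listed 53647 genes, of which 81 symbols belonged to more than 1 gene ID, and 29956 barcodes with at least 500 UMIs. Gene names were those of the count tables, and no coordinates were used. The totals per library were 153016369 and 152625351 UMIs (IgG) and 152457679 and 170539226 UMIs (anti-CD8), and the median per barcode was 21977, 20661, 17480 and 18636 UMIs in the same order. Counts of each pair of libraries differed beyond sampling noise, with chi-square per degree of freedom between 31.9 and 53.3, so no library was a copy of another. The smallest value was that of IgG replicate 2 with anti-CD8 replicate 2. It was 34.1 between the IgG libraries and 46.8 between the anti-CD8 libraries, so the libraries did not group by antibody on this measure.

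Barcodes with at least 300 genes and at most 20% mitochondrial UMIs were kept. The highest Scrublet doublet scores, 0.8% of a library per 1000 cells, were then removed (332, 353, 511 and 562 barcodes), which left 6108, 6290, 7481 and 7816 cells, or 27695 in total. Cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2 (resolution 1, 15 neighbours, 30 principal components of 3000 variable genes). Cd8a, Cd8b1, T-cell receptor, immunoglobulin and sex-linked genes were left out of the variable genes, and CD8 was no marker of any class, so the T-cell class was not defined by the antibody's target. The 28 clusters were named from marker lists, as microglia-like, T-cell-like and so on; the text gives the short names. The markers were fixed before the data were examined; the thresholds for naming were set afterwards. A cluster took a name at a mean log2 fold of at least 1.5 over its markers, with a margin of 0.3 over the next class. Clusters of the microglia and macrophage lineage were called microglia where at least 5 of the 10 microglia markers were at least 2 times their level in the macrophage cluster. This threshold kept apart 2 clusters led by Spp1, Gpnmb and Lpl, which were analysed as Spp1-high myeloid cells (21.3% of IgG and 20.8% of anti-CD8 cells on average). Cluster 19 stayed unnamed because astrocyte and oligodendrocyte-lineage genes led it together. Cluster 10, counted with the microglia, and cluster 16, counted with the pericytes, had a median depth of 0.163 and 0.096 times that of their libraries and were kept because their own markers led them.

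Shares of cells were tested with the quasi-likelihood test of edgeR 4.0.16 on cells per class and library, without composition scaling and with Benjamini-Hochberg adjustment over classes. Exact binomial intervals at 95% beside single libraries cover counting error. The share of T cells with at least 1 UMI of Cd8a or Cd8b1 was also read after each cell was thinned to 2000 UMIs, a depth set after seeing the data. For gene expression, UMI counts were summed per library and class and tested with edgeR's quasi-likelihood test (TMM scaling, edgeR's expression filter, 2 libraries against 2), in classes with at least 20 cells in each of the 4 libraries. A gene was called at an adjusted p under 0.05. Levels of named genes are TMM-normalised CPM (counts scaled to the library's total) of the class. They are given as mean ± SD over the 2 libraries of a group. Log2 fold changes are anti-CD8 over IgG. Their standard error (SE) was derived from the test, as the absolute log2 fold change divided by the square root of the F statistic. Each adjusted p of a gene comes from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment within the class unless another tool is named. The difference of the antibody effect between microglia and macrophages was tested as an interaction in 1 fit with the library as a block.

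Gene lists were fixed before the data were examined: cytotoxic effector, tissue residence and exhaustion, CD4 helper and regulatory T cell, gamma-delta T cell, type I interferon response, interferon-gamma response, MHC class I presentation, MHC class II presentation, disease-associated microglia, homeostatic microglia, inflammatory cytokines and chemokines, lipid handling, complement and phagocytosis, repair growth factors, cholesterol synthesis, fibrotic matrix, basement membrane, reactive astrocyte, endothelial activation, blood-brain barrier, proliferation, glycolysis, dissociation stress and immediate early, haemoglobin and sex-linked genes. Myelin and disease-associated oligodendrocyte lists were also fixed, but no cluster was named oligodendrocyte, and neither list was tested. All 405 list genes were found, 4 of them by gene ID. Each list was tested in the classes chosen for it with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of the class; the Spp1-high class was given the microglia lists after it had been seen. Camera with an estimated correlation and fry were run beside it.

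Genes named in the text followed a rule fixed before the data were examined. These were Cd8a, Cd8b1, Cd4 and Cd3e in T cells; in each class up to 10 called genes per direction with the largest change, with both anti-CD8 libraries on one side of both IgG libraries and a mean log2 CPM of at least 4, leaving out predicted gene models and ribosomal, mitochondrial and haemoglobin genes; where fewer than 3 passed, the 3 with the smallest p; and up to 4 members of each list with the smallest p. Some genes that the rule takes are not reported here. Members of families with near-identical copies (T-cell receptor gamma, histone, MHC class I and some chemokine genes) are uncertain where counting could split reads between copies.

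The tests were checked on simulated counts drawn from the means, depths and spread of each class, with 200 genes changed by known folds. At 2 against 2 libraries, edgeR called 47.6% of the genes changed 2-fold in T cells, 49.3% in neurons, 72.1% in microglia, 64.5% in Spp1-high myeloid cells, 68.2% in macrophages, 69.1% in endothelial cells, 64.5% in pericytes, 54.8% in ependymal cells, 13.6% in dendritic cells and 54.1% over all cells, and no gene in the wrong direction. At 1.5-fold it called 14.3% in T cells and 57.7% in microglia. Unchanged genes made up 18.6% of all calls on the simulated counts in dendritic cells, 17.5% in neurons (20 of 114 calls), 15.6% in microglia, 12.2% over all cells and 10.5% in T cells, and 4.3% to 8.1% in the other classes, at a nominal 5%. With no gene changed, the calls numbered 8 in Spp1-high myeloid cells, 6 in microglia, 5 over all cells, 2 each in macrophages, pericytes and ependymal cells, 1 each in neurons and endothelial cells and 0 in T cells and dendritic cells.

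The alternatives were each library left out in turn, no doublet removal, a stricter cell filter (500 genes, 10% mitochondrial UMIs), Leiden resolution 2, the replicate number as a block, median-ratio size factors in edgeR, no expression filter, DESeq2 1.42.0, equal numbers of cells per library, immune cells as the denominator or TMM scaling of shares, and at least 2 CD8 UMIs per cell. Alternatives chosen after seeing the data were the largest cluster of T cells or neurons alone, T cells with or without a CD8 UMI, and microglia or all cells without the interferon cluster. The markers that name each class were also read in the sums of the other classes, after the data had been seen. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3 and the package data.table (1.17.8).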

Results

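The data were single-cell transcriptomes of the lesion segment of the aged mouse spinal cord, 28 days after injury, from mice given control IgG or an antibody against CD8 (2 libraries each). The libraries held 153016369 and 152625351 UMIs (IgG) and 152457679 and 170539226 UMIs (anti-CD8). After filtering, there were 6108 and 6290 cells (IgG) and 7481 and 7816 cells (anti-CD8), with a median of 21950.5, 20469.5, 17284 and 18365.5 UMIs per cell in the same order. Microglia, the resident macrophages of the nervous system, made up 50.4% ± 6.36 of IgG cells and 50.4% ± 3.18 of anti-CD8 cells (SD, n = 2). Spp1-high myeloid cells made up 21.3% ± 1.31 and 20.8% ± 0.791. T cells, NK cells, dendritic cells, monocyte/macrophages, endothelial cells, pericytes with smooth muscle, ependymal cells and neurons were also found, with few fibroblasts and neutrophils. The comparison of anti-CD8 with IgG asks what the antibody changed in the cells of the lesion.

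CD8 transcripts, which encode the antibody's target, were found in a smaller share of T cells after anti-CD8. A UMI of Cd8a or Cd8b1 was present in 281 of 337 T cells (83.4%, exact 95% interval 79.0 to 87.2) and 502 of 731 (68.7%, 65.2 to 72.0) in the IgG libraries, and in 36.0% of 422 T cells (31.4 to 40.8) and 91 of 276 (33.0%, 27.5 to 38.9) in the anti-CD8 libraries. The group means of this CD8 share of T cells were 76.0% ± 10.4 and 34.5% ± 2.16 (SD, n = 2), a difference of -41.5 percentage points. In microglia, which should lack these transcripts, the share was 0.567%, 1.21%, 0.139% and 0.17% at a higher median depth (20727, 20548, 16357 and 17546 UMIs, against 7276, 7028, 5965.5 and 6806 in T cells). With each cell thinned to 2000 UMIs, the shares in T cells were 73.4% and 59.2% for IgG and 30.9% and 24.6% for anti-CD8, after 3, 23, 30 and 20 shallower cells were left out. An exact permutation of 2 against 2 libraries cannot give a two-sided p below 0.33, so it cannot pass a threshold of 0.05, although both anti-CD8 libraries lay below both IgG libraries.

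Within the T-cell sums, scaled to each library's T-cell total without TMM, Cd8a stood at 334 and 238 CPM in IgG and at 173 and 93.9 in anti-CD8, and Cd8b1 at 699 and 488 against 269 and 157. Cd8b1 fell, with a log2 fold change of -1.50 (SE 0.24, adjusted p = 0.0273; 606 ± 165 to 213 ± 80.2 CPM with TMM), while Cd8a did not pass the threshold (-1.11, adjusted p = 0.084; 3.27e-05 to 0.0295 with any 1 library left out). Cd4, the co-receptor of helper T cells, was at 8.41 and 39.1 CPM in IgG and 66.8 and 56.6 in anti-CD8 (log2 fold change 1.23, adjusted p = 0.27; 2.83 and 1.12e-05 without IgG replicate 2). Cd3e, a subunit common to T-cell receptors, was at 468 and 485 against 418 and 368 (adjusted p = 0.29). The Cd8b1 call did not hold without doublet removal (log2 fold change -1.52, adjusted p = 0.088) or with DESeq2 (-1.51, adjusted p = 0.051).

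**Figure D1:**
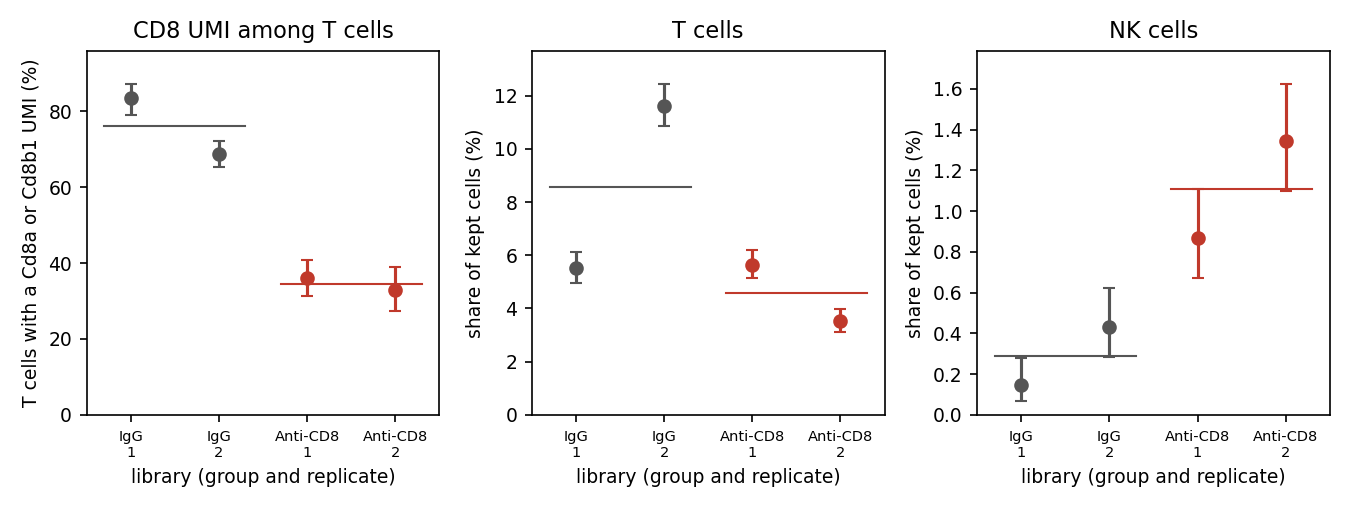
Share of T cells with a Cd8a or Cd8b1 UMI, and shares of T cells and NK cells among all kept cells, in percent, for each of the 4 libraries (points, with exact 95% binomial intervals; lines are group means). The CD8 share was 83.4% and 68.7% in the IgG libraries and 36.0% and 33.0% in the anti-CD8 libraries.

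NK cells, cytotoxic lymphocytes without a T-cell receptor, were the 1 class whose share of all cells passed the threshold. They made up 0.288% ± 0.199 of IgG cells (9 and 27 cells) and 1.11% ± 0.336 of anti-CD8 cells (65 and 105 cells; SD, n = 2), a log2 fold change of 1.93 (SE 0.56, adjusted p = 0.045 by edgeR's quasi-likelihood test over cells per library). T cells made up 8.57% ± 4.32 of IgG cells and 4.59% ± 1.49 of anti-CD8 cells (log2 fold change -0.90, adjusted p = 0.34; -0.27 without IgG replicate 2). The libraries overlapped, with 5.52% and 11.6% against 5.64% and 3.53%. Dendritic cells were at 0.475% and 0.832%, endothelial cells at 5.50% and 6.47%, monocyte/macrophages at 5.51% and 6.31%, ependymal cells at 2.47% and 3.16%, pericytes at 2.70% and 3.05%, neurons at 2.12% and 1.80%, fibroblasts at 0.128% and 0.196%, and neutrophils at 0.040% and 0.065%; none of these passed. The unnamed cluster held 0.545% and 1.22% (adjusted p = 0.34). The adjusted p for NK cells ranged from 0.019 with TMM scaling of the class counts to 0.484 without anti-CD8 replicate 2. It was 0.428 without IgG replicate 1, 0.099 without anti-CD8 replicate 1, 0.218 among immune cells, 0.087 with the stricter cell filter and 0.477 at Leiden resolution 2.

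In T cells 91 genes were higher and 23 lower after anti-CD8, of 10481 tested. Among those that rose were Il23r, a cytokine receptor of type 17 lymphocytes (37.7 ± 1.33 to 122 ± 17.1 CPM, log2 fold change 1.69, SE 0.15, adjusted p = 0.0042), Serpinb1a, a protease inhibitor (42.3 ± 11.2 to 148 ± 33.2 CPM, 1.78), Tmem176a (109 ± 8.25 to 335 ± 74.3 CPM, 1.62) and Ppp1r14c (1.96). Ankrd6, Pxdc1, Trim69, Pard3 and Cnnm2 rose by between 1.65 and 1.80 on the log2 scale. Genes that fell included the histone genes H1f5 (-1.91) and H2ac24 (-1.44), the T-cell receptor gamma genes Trgc2 (144 ± 1.25 to 55.1 ± 2.18 CPM, -1.39, adjusted p = 0.0042) and Trgv2 (-1.13), the interferon-stimulated gene Ifi27l2a (-1.25), and Cntln, Armc7 and Mctp2 (-1.28 to -1.13), with BE692007 (147 ± 8.23 to 73.0 ± 10.3 CPM). Trgc2 and Trgv2 were at 0.15 and 0.34 in T cells without a CD8 UMI, against -1.35 and -1.39 in those with one, and passed in neither part. Il23r and Icos were also among the leading genes of the smaller T-cell cluster 18, and H1f5 of cluster 26. Cluster 18 held 23 and 70 cells in IgG and 104 and 66 in anti-CD8. The 114 calls became 266 without IgG replicate 1, 332 without IgG replicate 2, 261 without anti-CD8 replicate 1, 324 without anti-CD8 replicate 2 and 19 without doublet removal. In the largest cluster alone, 14 genes were called, and 1 and 0 in T cells with and without a CD8 UMI (679 and 242 at an unadjusted p under 0.05).

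**Figure D2:**
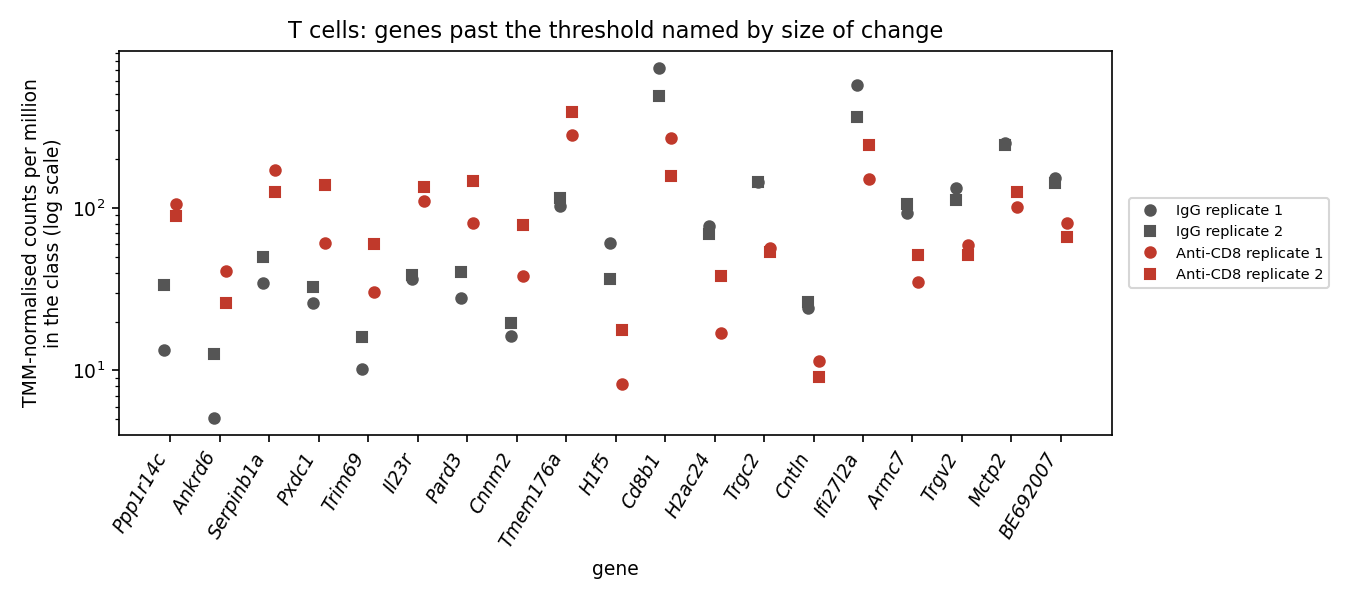
TMM-normalised CPM in T cells (log axis) of the called genes named by size of change, for each of the 4 libraries. Il23r went from 37.7 in IgG to 122 in anti-CD8 on average, and Trgc2 from 144 to 55.1.

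By gene list, the CD4 helper and regulatory T-cell genes were higher after anti-CD8, with 9 of 9 members above 0 and a median log2 fold change of 0.83. No list in T cells passed with an estimated correlation, where the adjusted p of this list was 0.117. Of its members, 3 rose, and 5 did when adjusted over the list alone. The 3 were Il2ra, a subunit of the interleukin-2 receptor (38.8 ± 7.94 to 118 ± 24.8 CPM, 1.57), Icos, a co-stimulatory receptor (0.85), and Cd40lg, the ligand by which helper cells activate other immune cells (1.06). Markers of other classes were also higher in the T-cell sums. Those of type 2 innate lymphoid cells had a median of 1.04 (4 of 4 measured above 0). Together they stood at 91.0 and 116 CPM in IgG and 179 and 145 in anti-CD8, without TMM. Endothelial (4 of 4) and pericyte markers (3 of 3) each had a median of 0.72. The endothelial markers together stood at 59.63 and 74.5 against 104.3 and 120.4, and the pericyte markers at 28.28 and 27.38 against 52.94 and 29.09. Cytotoxic effector genes were lower, with 19 of 20 members below 0 (median -0.27; adjusted p = 0.197 with an estimated correlation). Nkg7, a granule protein, fell (-0.69, adjusted p = 0.013), and 5 members fell when adjusted over the list alone. Gzmk (-0.58), the pore-forming Prf1 (-0.68) and the chemokine Ccl5 (-0.68) did not pass over all genes, with adjusted p between 0.082 and 0.094. The tissue residence and exhaustion list was lower on test but had 8 of 15 members below 0 (median -0.15; adjusted p = 0.446 with an estimated correlation). Tox, a transcription factor of exhausted T cells, fell (798 ± 124 to 411 ± 11.3 CPM, -0.96), and the inhibitory receptors Havcr2 (-1.34) and Lag3 (-1.42) did not pass. Dissociation stress and immediate early genes were higher (19 of 22, median 0.32; adjusted p = 0.117 with an estimated correlation), and Atf3 (1.24), Egr1 (0.88) and Klf4 (0.95) rose. The gamma-delta list was not called (median 1.25, adjusted p = 0.078), though it was without IgG replicate 2 (2.07) or anti-CD8 replicate 2 (1.54), and its median was -0.04 without anti-CD8 replicate 1. Its member Trgc1 did not pass (1.40). Type I interferon genes (21 of 23 members below 0, median -1.21), proliferation genes (18 of 19, -0.57), MHC class I genes (15 of 16, -0.27) and interferon-gamma genes (14 of 19, -0.16) were also lower, with Xaf1 (-1.60) and H2-T23 (-0.60) not passing on their own. With an estimated correlation the adjusted p was 0.44 for type I interferon and proliferation genes, 0.446 for MHC class I genes and 0.564 for interferon-gamma genes. Camera with a preset correlation gave adjusted p values from 3.53e-13 (CD4 list) to 0.0228 (interferon-gamma list).

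In T cells split by their own CD8 UMIs, a split chosen after seeing the data, the CD4 list (median -0.28 with and 0.03 without a CD8 UMI) and the cytotoxic list (0.01 and 0.01) were no longer called. Without a CD8 UMI the stress (0.03), interferon-gamma (0.07), MHC class I (-0.01), proliferation (-0.04) and residence lists (-0.16) were not called either. The adjusted p values were 0.337 and 0.578 for the CD4 list and 0.631 and 0.894 for the cytotoxic list. Single genes turned too, with Nkg7 at 0.20 in T cells without a CD8 UMI and Cd40lg at -0.16 in those with one. The cytotoxic and proliferation calls also ended in the largest cluster alone (medians -0.01 and -0.08, adjusted p = 0.208 and 0.366). Type I interferon genes remained lower in both parts (-1.11 and -0.83), though their median without IgG replicate 1 was -0.25. The interferon-gamma call ended without IgG replicate 1 (adjusted p = 0.353) or anti-CD8 replicate 1 (0.527), the MHC class I call without IgG replicate 1 (0.0533), the proliferation call without anti-CD8 replicate 1 (0.16) and the residence call without anti-CD8 replicate 2 (0.416).

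In microglia no single gene was called, and several lists were called at the preset correlation but none with an estimated correlation. Disease-associated microglia genes, a programme of lipid and phagocytic genes, were lower after anti-CD8 (20 of 22 members below 0, median -0.14; adjusted p = 0.455 with an estimated correlation). Ank went from 137 ± 8.72 to 93.2 ± 8.13 CPM (log2 fold change -0.55, SE 0.08), Cst7 from 735 ± 18.2 to 534 ± 54.9 CPM (-0.46) and the lipase Lpl from 523 ± 31.8 to 382 ± 33.3 CPM (-0.45). These had adjusted p values of 0.23 to 0.32, and 4 members fell when adjusted over the list alone. Microglial clusters 2 and 3, led by Crybb1, Slc2a5 and Siglech, held a higher share of all cells in both anti-CD8 libraries, without passing. Cluster 3 held 5.98% and 7.41% in IgG and 9.38% and 9.39% in anti-CD8. Cluster 2 held 7.32% and 9.57% against 9.86% and 11.3%. Clusters 4, 5, 10 and 12, with Siglech and P2ry12 among their leading genes, overlapped between the groups. A different mix of microglial clusters was not tested as the source of the lower disease-associated list. MHC class I genes were lower as well (15 of 16, median -0.18; adjusted p = 0.455 with an estimated correlation), with B2m, the light chain of class I molecules, at -0.32. Lists of glycolysis (12 of 14 below 0, -0.12), lipid handling (12 of 17, -0.06; the cholesterol exporter Abcg1 -0.36) and interferon-gamma response (16 of 19, -0.23; Iigp1 -2.16) were lower, and cholesterol synthesis was higher (14 of 18, 0.11; Cyp51 0.32). With an estimated correlation the adjusted p was 0.541 for glycolysis and cholesterol synthesis and 0.455 for lipid and interferon-gamma genes. The median of the interferon-gamma list was -0.11 without IgG replicate 1, where Iigp1 was at -0.57, -0.11 without anti-CD8 replicate 1 and -0.36 without IgG replicate 2. Type I interferon genes had 24 of 24 members below 0 (median -1.27; adjusted p = 0.455 with an estimated correlation), but their IgG libraries lay far apart, as in Rsad2 (28.1 ± 24.9 to 8.18 ± 2.54 CPM) and Ifi44 (4.68 ± 5.49 to 0.755 ± 0.061 CPM). Without IgG replicate 1 the median of this list was -0.07 and the call ended (adjusted p = 0.135). That library held 399 of its cells in an interferon-high microglial cluster, against 57, 37 and 90 in the others. Markers of other classes moved in the microglia sums as well. Neutrophil markers had a median of -5.16 (6 of 7 measured below 0) and together stood at 452 CPM in IgG replicate 1 and 233, 227 and 221 in the other libraries, without TMM. T-cell markers had a median of -0.44 (11 of 13 below 0) but together stood at 14.56 and 16.4 CPM in IgG and 13.71 and 14.83 in anti-CD8. B-cell markers had a median of 0.48 (7 of 8 above 0), at 219.6 CPM in anti-CD8 replicate 1 against 90.8, 90.6 and 86.3.

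Over all 18177 genes tested in microglia, edgeR called 0 at the adjusted threshold, 1552 had an unadjusted p under 0.05, and DESeq2 called 79. The smallest p values among higher genes belonged to Ly6k (0.679 ± 0.016 to 5.84 ± 2.47 CPM, adjusted p = 0.16), Chst8 (0.88) and Tex14 (0.50), and among lower genes to Sox7 (1.88 ± 0.036 to 0.383 ± 0.033 CPM, adjusted p = 0.14), Baiap2l2 (-1.25) and Rgs1 (-0.43, adjusted p = 0.19). The edgeR count was 18 without IgG replicate 1, 287 without IgG replicate 2, 3 without anti-CD8 replicate 1 and 53 without anti-CD8 replicate 2. The preset-correlation p of the called lists, adjusted, ranged from 7.79e-17 for type I interferon to 0.0133 for cholesterol synthesis. Homeostatic (median -0.04), complement (-0.07), inflammatory (-0.01), MHC class II (-0.04), repair growth factor (-0.02), proliferation (-0.04) and stress (-0.05) lists were not called; the means of the complement (0.03) and inflammatory lists (0.004) had the other sign. With 1 library left out some were called in opposite directions, as MHC class II (-0.28 without IgG replicate 1, 0.30 without IgG replicate 2) and inflammatory genes (-0.13 without IgG replicate 1, -0.16 without anti-CD8 replicate 2, 0.16 without IgG replicate 2, 0.08 without anti-CD8 replicate 1). Homeostatic (-0.08 and -0.12 without IgG or anti-CD8 replicate 1), stress (-0.13 and -0.16 without IgG replicate 1 or anti-CD8 replicate 2), repair (-0.10 and -0.14, the same libraries) and proliferation genes (-0.14 without anti-CD8 replicate 2) were called lower. Leaving out a single library also ended the calls of cholesterol synthesis (IgG replicate 1, adjusted p = 0.34; anti-CD8 replicate 1, 0.072), glycolysis (IgG replicate 2, 0.19; anti-CD8 replicate 1, 0.15), lipid handling (IgG replicate 1, 0.16; anti-CD8 replicate 1, 0.13) and interferon-gamma (anti-CD8 replicate 1, 0.0633; without the interferon-high cluster 0.0538).

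**Figure D3:**
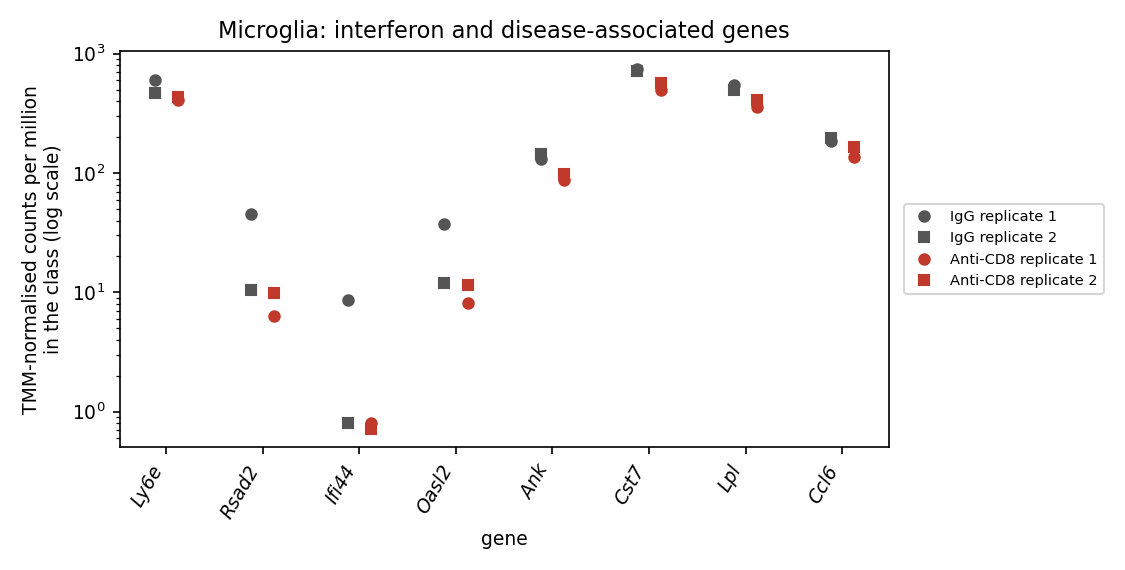
TMM-normalised CPM in microglia (log axis) of 8 list members, for each of the 4 libraries. Ank, Cst7 and Lpl were lower in both anti-CD8 libraries than in both IgG libraries, without passing the adjusted threshold.

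Spp1-high myeloid cells, led by the matrix protein gene Spp1 and the lysosomal gene Gpnmb, had no called gene, and several lists were called at the preset correlation but none with an estimated correlation. Type I interferon genes were lower (24 of 24 members below 0, median -0.47; adjusted p = 0.339 with an estimated correlation; 12 fell when adjusted over the list alone), and Ly6e went from 330 ± 43.1 to 235 ± 17.8 CPM (-0.49). MHC class I genes (15 of 16, -0.14; B2m -0.34), disease-associated genes (21 of 22, -0.08; the protease Ctsb -0.22 and Cd9 -0.20), lipid handling (15 of 17, -0.11), repair growth factors (11 of 13, -0.07; the stress cytokine Gdf15 91.4 ± 8.27 to 55.3 ± 5.56 CPM), stress (15 of 22, -0.07), homeostatic (11 of 14, -0.09) and complement genes (12 of 17, -0.07) were lower. With an estimated correlation the adjusted p was 0.339 for disease-associated, lipid, repair and stress genes, 0.426 for MHC class I, 0.499 for homeostatic and 0.516 for complement genes. Cholesterol synthesis was higher (14 of 18, 0.23; adjusted p = 0.35 with an estimated correlation), with the synthesis enzyme Cyp51 at 0.47. Endothelial markers in these sums had a median of 0.44 (8 of 10 above 0) but together stood at 175.7 and 145.2 CPM in IgG and 157.6 and 161.2 in anti-CD8, without TMM. B-cell markers had a median of 0.21 (5 of 7) and together stood at 108 CPM in anti-CD8 replicate 1 and 60.2, 62.1 and 60.8 in the other libraries, without TMM. The preset-correlation p, adjusted, ranged from 1.09e-20 to 0.049. Glycolysis (-0.06), inflammatory (-0.07), interferon-gamma (-0.04), MHC class II (-0.13) and proliferation lists (0.01, mean -0.005) were not called. MHC class II was called in opposite directions without IgG replicate 1 (-0.53) and IgG replicate 2 (0.23), and inflammatory genes were lower without IgG replicate 1 (-0.11) or anti-CD8 replicate 2 (-0.08) and glycolysis without IgG replicate 1 (-0.12). EdgeR called 0 of 16014 genes, with 1186 at an unadjusted p under 0.05, and DESeq2 called 36; Ly6k (3.58), Gdf15 (-0.73), Cxcr4 (-0.49) and Il18bp (-0.64) had the smallest adjusted p (0.072), and Chst8 was at 0.71. The count was 72 without IgG replicate 1, 88 without IgG replicate 2, 73 without anti-CD8 replicate 1 and 88 without anti-CD8 replicate 2. The complement call ended without IgG replicate 2 (adjusted p = 0.46) or anti-CD8 replicate 2 (0.76), the homeostatic call without anti-CD8 replicate 2 (0.41) and the stress call without anti-CD8 replicate 1 (0.24); at Leiden resolution 2 the complement (0.28) and homeostatic (0.565) calls ended, and without doublet removal the complement call (0.0675).

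Monocyte/macrophages, which include cells recruited from blood, had higher MHC class II genes after anti-CD8 (7 of 7 members above 0, median 0.23; adjusted p = 0.527 with an estimated correlation), with H2-Ab1 at 799 ± 139 and 982 ± 14.2 CPM and Ciita, the master regulator of class II genes, at 8.25 ± 2.20 and 12.8 ± 1.49 CPM. Type I interferon (21 of 24 below 0, -0.25), stress (17 of 22, -0.13), lipid handling (13 of 17, -0.12) and disease-associated genes (18 of 22, -0.08; Lpl -0.41, Spp1 -0.40) were lower. With an estimated correlation each of these also had an adjusted p of 0.527. The chemokine genes Cxcl13 (4.61 ± 2.27 to 24.9 ± 12.2 CPM), Cxcl9 (1.09 ± 1.54 to 13.6 ± 8.72 CPM) and Ccl8 (13.3 ± 3.63 to 30.6 ± 17.6 CPM) and the monocyte gene Plac8 (0.789 ± 0.406 to 20.1 ± 13.9 CPM) had higher means that did not pass (adjusted p = 0.44 to 0.93), and Lima1 was at -0.76. At Leiden resolution 2, where 1242 of the 1652 macrophages joined the Spp1-high class, Cxcl13 was at -0.26. The cells that kept the macrophage name there were 55 of 275 and 94 of 410 in IgG and 115 of 436 and 145 of 531 in anti-CD8, a higher share in both anti-CD8 libraries than in both IgG libraries. Their cluster was led by Mrc1 and by genes of the MHC class II list, among them H2-Eb1, H2-Aa, H2-Ab1, Cd74 and Ciita. A larger share of such cells was not tested as the source of the higher MHC class II list. Macrophage markers had a median of 0.30 in the class (8 of 11 above 0), at 1521 and 1462 CPM together in IgG and 1752 and 1465 in anti-CD8. B-cell markers together stood at 138 CPM in anti-CD8 replicate 1 and 106, 105 and 102 in the other libraries, both without TMM. EdgeR called 0 of 12375 genes, with 648 at an unadjusted p under 0.05, and DESeq2 called 3. The count was 0 without IgG replicate 1, 1 without IgG replicate 2, 16 without anti-CD8 replicate 1 and 55 without anti-CD8 replicate 2. List calls had adjusted p from 6.13e-07 to 0.00186 at the preset correlation. Leaving out IgG replicate 1 ended those of type I interferon (median 0.08, adjusted p = 0.297), MHC class II (0.09, 0.146), lipid handling (-0.02, 0.659) and disease-associated genes (-0.04, 0.356), and leaving out anti-CD8 replicate 1 the last (0.618). At Leiden resolution 2 the MHC class II, lipid, disease-associated and stress calls ended (adjusted p = 0.151 to 0.797). Complement (0.07), glycolysis (0.03), inflammatory (0.02), interferon-gamma (-0.16), MHC class I (-0.05), proliferation (-0.05) and repair lists (-0.04) were not called. The mean of the interferon-gamma list was 0.12 and that of the inflammatory list -0.009, against medians of the other sign; adjusted over the list alone, 2 interferon-gamma genes rose and 1 fell. Inflammatory genes were called lower without IgG replicate 1 (-0.19) and higher without IgG replicate 2 (0.17), complement genes higher (0.15) and MHC class I genes lower (-0.08) without anti-CD8 replicate 2, and repair genes lower without IgG replicate 2 (-0.11) or anti-CD8 replicate 2 (-0.26). The antibody effect differed between macrophages and microglia for 2 of 17443 genes, Cxcl13 and S100a9. Of the S100a9 UMIs in microglia, 7165 came from IgG replicate 1, against 23, 15 and 53 in the other libraries.

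Dendritic cells, which present antigen to T cells, had lower inflammatory cytokine and chemokine genes after anti-CD8, a call that did not hold with an estimated correlation (adjusted p = 0.164). Of 13 measured members 12 lay below 0 (median -0.83), and 5 fell when adjusted over the list alone. The median was -0.33 without IgG replicate 2 and -0.51 without anti-CD8 replicate 1. The class was small (26 and 33 cells in IgG, 90 and 36 in anti-CD8), and B-cell markers together, scaled to the class total without TMM, stood at 643 and 343 CPM in IgG and 16040 and 66.8 in anti-CD8. Ighm, an immunoglobulin gene chosen after its values were seen, led the cluster and was at 179 and 73.0 CPM in IgG and 16525 and 64.1 in anti-CD8. The cluster's mean log2 fold was 4.19 over dendritic-cell markers and 3.77 over B-cell markers, and no cluster was named B cell. The class therefore cannot be read as dendritic cells alone, above all in anti-CD8 replicate 1. Microglia markers had a median of 0.41 (7 of 7 measured above 0) and together stood at 591.0 and 629.8 CPM in IgG and 981.5 and 543.0 in anti-CD8, without TMM. Il1b, a pro-inflammatory cytokine, went from 3992 ± 839 to 2242 ± 418 CPM (-0.83), and the chemokine genes Ccl4 from 450 ± 98.2 to 149 ± 43.6 CPM (-1.58) and Cxcl2 from 150 ± 36.6 to 48.9 ± 1.68 CPM (-1.60). Ccrl2, a chemokine-binding receptor, was at 421 ± 23.8 and 149 ± 7.08 CPM (-1.51), and Odc1, an enzyme of polyamine synthesis, at 86.3 ± 18.9 and 263 ± 56.0 CPM (1.59). None passed over all genes (adjusted p = 0.30 to 0.70). The interferon-gamma list was lower (5 of 6, -0.43; adjusted p = 0.313 with an estimated correlation), and MHC class I (-0.07), MHC class II (-0.27), type I interferon (-0.33) and stress lists (0.11) were not called, though type I interferon genes were called lower without IgG replicate 2 (-1.42) or anti-CD8 replicate 2 (-0.74) and had a median of 0.33 without IgG replicate 1. The preset-correlation p, adjusted, was 1.02e-11 for inflammatory and 0.0165 for interferon-gamma genes. EdgeR called 0 of 6275 genes, with 393 at an unadjusted p under 0.05, and DESeq2 called 5; the count was 0 without IgG replicate 1, 16 without IgG replicate 2, 33 without anti-CD8 replicate 1 and 45 without anti-CD8 replicate 2. The interferon-gamma call ended without IgG replicate 1 (adjusted p = 0.63), anti-CD8 replicate 1 (0.18) or anti-CD8 replicate 2 (0.27) and without doublet removal (0.36).

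Endothelial cells, which line the vessels, had lower activation genes after anti-CD8 (10 of 12 members below 0, median -0.33, adjusted p = 0.404 with an estimated correlation). Among them were Lrg1 (45.2 ± 15.5 to 24.2 ± 2.24 CPM) and the adhesion molecule Vcam1 (213 ± 64.5 to 148 ± 34.5 CPM). For Vcam1 the libraries of the groups overlapped. The chemokine Cxcl10 was at 184 and 14.2 CPM in IgG and 17.7 and 27.0 in anti-CD8, with a log2 fold change of 0.64 without IgG replicate 1. Interferon-gamma (14 of 19, -0.29) and MHC class I genes (15 of 16, -0.16) were lower and MHC class II genes higher (6 of 6, 0.77; H2-Ab1 10.7 ± 1.95 to 22.6 ± 13.8 CPM). Each of these had an adjusted p of 0.404 with an estimated correlation. Blood-brain barrier (-0.01, mean 0.002), basement membrane (-0.08), proliferation (-0.07, mean 0.01) and stress lists (0.06) were not called, though barrier genes were called higher without IgG replicate 1 (0.06) and stress genes without IgG replicate 2 (0.17). EdgeR called 0 of 13918 genes, with 666 at an unadjusted p under 0.05, and DESeq2 called 4. The smallest p values included those of Sox18, a vascular transcription factor (222 ± 18.2 to 120 ± 17.3 CPM, adjusted p = 0.11), Abca4 (0.88), Angpt2, a regulator of vessel remodelling (0.77), Ccl4 (0.88, adjusted p = 0.14) and the prostaglandin synthase Ptgs2 (-0.81). Ccl4 was also a leading gene of microglial clusters, and microglia markers in the endothelial sums had a median of 0.31, with 7 of 8 measured above 0. Together these markers stood at 145.3 and 185.1 CPM in IgG and 184.1 and 194.1 in anti-CD8, without TMM. Fibroblast markers had a median of -0.26 (3 of 3 measured below 0). The count was 26 without IgG replicate 1, 115 without IgG replicate 2, 0 without anti-CD8 replicate 1 and 8 without anti-CD8 replicate 2. List calls had adjusted p from 3.65e-06 to 7.43e-06 at the preset correlation. Activation and interferon-gamma calls ended without IgG replicate 1 (medians 0.09 and 0.03, adjusted p = 0.7 and 0.21) or anti-CD8 replicate 1 (0.28 and 0.24), the MHC class I call without IgG replicate 1 (0.079) or anti-CD8 replicate 2 (0.094) and the MHC class II call without anti-CD8 replicate 1 (0.6).

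In pericytes and smooth muscle cells, which wrap the vessels, 1 of 12401 genes was called. Ptgs2 fell from 207 ± 12.9 to 99.8 ± 5.11 CPM (log2 fold change -1.05, SE 0.12, adjusted p = 0.017), while simulated counts with no gene changed gave 2 calls in this class. At Leiden resolution 2, 243 of the 802 cells of the class (24 and 58 in IgG, 30 and 131 in anti-CD8) were named endothelial, and Ptgs2 still fell in the remaining cells (-1.02, adjusted p = 0.018). Endothelial markers together stood at 10980 and 11590 CPM in IgG and 11430 and 11100 in anti-CD8, without TMM. Pericyte markers stood at 11520 and 11630 against 13110 and 11690. The largest remaining cluster had a mean log2 fold of 4.61 over pericyte markers and 3.28 over endothelial markers. Ptgs2 was also lower in endothelial cells, without passing. Endothelial RNA in these sums therefore cannot be told apart from a change in pericytes. Irf1, an interferon-induced transcription factor (241 ± 3.04 to 146 ± 0.768 CPM), and Sox18 (145 ± 11.3 to 77.8 ± 10.6 CPM) did not pass (adjusted p = 0.11), and Tex14 was at 0.62. MHC class I (16 of 16 below 0, -0.18; H2-T23 -0.60), interferon-gamma (14 of 17, -0.21), stress (17 of 22, -0.11) and fibrotic matrix genes (15 of 21, -0.23; the matricellular gene Ccn2 -0.71) were lower, and basement membrane genes were not called (-0.09; called lower without IgG replicate 2, -0.11). With an estimated correlation the adjusted p was 0.283 for MHC class I and interferon-gamma genes, 0.384 for fibrotic matrix and 0.387 for stress genes, against 1.44e-07 to 0.00135 at the preset correlation. Fibroblast markers, some of them also in the fibrotic matrix list, had a median of -0.55 in these sums, with 7 of 7 measured below 0. T-cell markers had a median of -1.24 (4 of 4 measured below 0) and monocyte/macrophage markers one of -0.92 (3 of 4). T-cell markers together stood at 25.13 and 50.97 CPM in IgG and 9.38 and 27.7 in anti-CD8, without TMM. Monocyte/macrophage markers stood at 107.4 and 57.13 against 35.96 and 63.56. The Ptgs2 call ended without anti-CD8 replicate 2 (adjusted p = 0.052), without doublet removal (1.0) and with equal cell numbers (0.593); the number of calls was 3 without IgG replicate 1, 49 without IgG replicate 2, 11 without anti-CD8 replicate 1 and 3 without anti-CD8 replicate 2. The fibrotic matrix call ended without IgG replicate 1 (median 0.29, adjusted p = 0.39), and the stress call without IgG replicate 1 (0.061) or anti-CD8 replicate 2 (0.26).

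Ependymal cells, which line the central canal, had lower MHC class I genes after anti-CD8 (15 of 16 members below 0, median -0.38), with H2-T23 at 35.6 ± 1.33 and 18.6 ± 3.38 CPM and B2m at 217 ± 15.8 and 155 ± 2.46 CPM, and 5 members fell when adjusted over the list alone. The adjusted p was 1.25e-14 at the preset correlation and 0.0547 with an estimated correlation. One gene of 14266 was called: the chemokine Ccl12 fell from 23.7 ± 5.65 to 2.90 ± 0.004 CPM (-3.02, SE 0.29, adjusted p = 0.0054), while simulated counts with no gene changed gave 2 calls in this class. Ccl12 was also a leading gene of microglial clusters, as was Acod1 (15.8 ± 1.61 to 2.03 ± 1.91 CPM), and the fibroblast gene Dcn was at 14.3 and 127 CPM in IgG against 0.171 and 0; both had an adjusted p of 0.25. Microglia markers in the ependymal sums had a median of 0.11, with 5 of 9 measured above 0. Neuron markers had a median of -0.66 (4 of 5 measured below 0) but together stood at 358.3 and 397.2 CPM in IgG and 358.9 and 334.5 in anti-CD8, without TMM. Markers of type 2 innate lymphoid cells had a median of -0.41 (3 of 3 below 0), at 70.98 and 73.86 against 50.38 and 63.78. Tgfb2, a growth factor, was at 0.67 and did not pass. The reactive astrocyte list was higher (10 of 16, 0.05, adjusted p = 0.0447; 0.268 with an estimated correlation), and interferon-gamma (-0.18) and stress lists (0.06) were not called. Both were called higher without IgG replicate 1 (0.15 and 0.35) and lower without IgG replicate 2 (-0.37 and -0.19), and interferon-gamma genes were lower without anti-CD8 replicate 2 (-0.12). The Ccl12 call ended without anti-CD8 replicate 1 (adjusted p = 0.069) and without doublet removal (log2 fold change -1.59, adjusted p = 1.0), and the reactive astrocyte call without anti-CD8 replicate 1 (median -0.09, 0.69). The number of calls was 172 without IgG replicate 1, 67 without IgG replicate 2, 0 without anti-CD8 replicate 1 and 4 without anti-CD8 replicate 2.

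In neurons 50 genes were higher and 38 lower after anti-CD8, of 13963 tested. Among the genes that fell were Cntn5, a neuronal adhesion molecule (255 ± 8.86 to 60.7 ± 5.87 CPM, log2 fold change -2.07, SE 0.16, adjusted p = 0.0011), the receptor kinase Alk (-2.05), the netrin receptor Unc5d (550 ± 159 to 149 ± 43.7 CPM, -1.88), Tafa1 (-1.82) and Luzp2 (-1.64). Genes that rose included the immediate early genes Fos (199 ± 21.4 to 431 ± 56.2 CPM, 1.12) and Fosb (33.6 ± 7.85 to 96.5 ± 31.4 CPM), Klf2 (1.38), and Rgs1 (1.69), Runx1 (1.39), Bcl2a1d (1.54) and Flt1 (1.55), which are typical of blood, immune or vascular cells. The stress and immediate early list was higher (22 of 22 above 0, median 0.80; 3 rose, and 13 when adjusted over the list alone), as were MHC class I (16 of 16, 0.67; 7 rose when adjusted over the list alone; H2-K1 0.98, B2m 0.82) and interferon-gamma genes (6 of 9, 0.27). The preset-correlation p, adjusted, was 6.6e-24, 4.99e-10 and 0.00787, and 0.118, 0.166 and 0.19 with an estimated correlation. Microglia markers in the neuron sums moved with the genes that rose: 9 of the 10 were measured, all 9 above 0 (median 0.89), with Cx3cr1 at 0.89. Of 8 endothelial markers measured, 7 lay above 0 (median 1.12). The smaller neuron cluster 24 held 11 and 11 cells in IgG and 25 and 23 in anti-CD8. The 88 calls became 266 without IgG replicate 1, 418 without IgG replicate 2, 30 without anti-CD8 replicate 1, 13 without anti-CD8 replicate 2, 1 without doublet removal, 19 with the stricter filter, 16 with equal cell numbers and 137 with DESeq2. Cntn5 passed under each of these and in the largest cluster alone. The interferon-gamma call ended without anti-CD8 replicate 2 (adjusted p = 0.36).

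Summed over all cells, MHC class I genes were lower after anti-CD8 (16 of 16 members below 0, median -0.17), as were interferon-gamma genes (15 of 20, -0.18), and the stress list was not called (0.04). The adjusted p was 1.41e-09 and 0.000106 at the preset correlation and 0.288 for both with an estimated correlation. Of 23675 genes edgeR called 0, with 996 at an unadjusted p under 0.05, and DESeq2 called 70. The count was 8 without IgG replicate 1, 5 without IgG replicate 2, 0 without anti-CD8 replicate 1 and 4 without anti-CD8 replicate 2. The interferon-gamma call ended without IgG replicate 1 (adjusted p = 0.34) or anti-CD8 replicate 1 (0.22). These sums move with cell composition as well as with expression.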

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

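The antibody effect differed between macrophages and microglia for 2 genes, by the test of the difference itself (edgeR's quasi-likelihood interaction, 17443 genes tested, 894 at an unadjusted p under 0.05), and no explanation was tested for either. For Cxcl13, a B-cell-attracting chemokine, the log2 effect in macrophages minus that in microglia was 2.89 (SE 0.20, adjusted p = 9.62e-06). Microglia held 76.3 and 83.6 CPM in IgG and 73.8 and 40.6 in anti-CD8, scaled to the class total without TMM, and macrophages 2.91 and 6.18 against 34.2 and 16.5. At Leiden resolution 2, Cxcl13 in macrophages had a log2 fold change of -0.26. For S100a9, a neutrophil calcium-binding protein, the difference was 9.98 (SE 1.20, adjusted p = 0.00688). In microglia 7165 of its UMIs came from IgG replicate 1, against 23, 15 and 53 in the others, and in macrophages anti-CD8 replicate 1 held 83, against 4, 2 and 5. The number of genes with such a difference was 6 without IgG replicate 1, 90 without IgG replicate 2, 48 without anti-CD8 replicate 1 and 108 without anti-CD8 replicate 2.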

How the results depend on the processing

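The sums of the largest cluster alone, of T cells with or without a CD8 UMI and without the interferon cluster were chosen after seeing the data, the T cells without a CD8 UMI before that result was known. The CD8 share of T cells differed by -34.2 to -48.9 percentage points under its alternatives. The 46 list calls kept their direction and side of the threshold with the stricter cell filter, and 44 without doublet removal. With a library left out, the lone library of its group is assumed to vary like the others. For each change below the cause was not tested. Dendritic cells limit detection most, since 13.6% of simulated 2-fold changes were called there.

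Log2 share changes with 1 library left out ran from -0.05 to 1.34 in dendritic cells, -0.04 to 0.47 in endothelial cells, -0.06 to 0.67 in ependymal cells, -0.12 to 0.14 in microglia, -0.05 to 0.49 in macrophages, 1.36 to 2.89 in NK cells, -0.61 to 0.27 in neurons, -0.10 to 0.03 in Spp1-high myeloid cells, -1.34 (without IgG replicate 1) to -0.27 (without IgG replicate 2) in T cells, where it was -0.90 with all libraries, 0.02 to 0.35 in pericytes, 0.17 to 1.24 in fibroblasts, 0.04 to 1.89 in neutrophils and 0.45 to 1.89 in the unnamed cluster. At Leiden resolution 2 they were -0.01 in microglia, -0.03 in pericytes, 0.01 in Spp1-high myeloid cells, 1.93 in NK cells and 0.52 in macrophages, which passed at neither resolution (0.20 at resolution 1). With TMM they were -0.05 in endothelial cells, -0.31 in microglia, -0.07 in macrophages and -0.10 in pericytes. Among immune cells they were 0.01 in Spp1-high myeloid cells and 1.96 in NK cells, whose value was 1.92 with the stricter filter.

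Counts of called genes with 1 library left out ran from 0 to 45 in dendritic cells, 0 to 115 in endothelial cells, 0 to 172 in ependymal cells, 3 to 287 in microglia, 0 to 55 in macrophages, 13 to 418 in neurons, 3 to 49 in pericytes, 72 to 88 in Spp1-high myeloid cells, 261 to 332 in T cells, 0 to 8 over all cells and 6 to 108 for the macrophage and microglia difference. Without the expression filter they were 155 in dendritic cells, 139 in endothelial cells, 135 in ependymal cells, 595 in microglia, 102 in macrophages, 675 in neurons, 96 in pericytes, 35 in Spp1-high myeloid cells and 612 in T cells. DESeq2 called 5, 4, 12, 79, 3, 137, 3 and 36 in the first 8 of these classes and 70 over all cells. Without doublet removal counts were 0 in ependymal cells and pericytes, 1 in neurons and 19 in T cells; with the stricter filter 2 in ependymal cells and 19 in neurons; with equal cells 1 in microglia, 2 in macrophages, 16 in neurons and 0 in pericytes; at Leiden resolution 2, 2 in macrophages. The largest cluster alone gave 1 in neurons and 14 in T cells, and T cells with and without a CD8 UMI gave 1 and 0.

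In the sums of all cells, deviations of same-numbered libraries from their group means correlated at -0.0026 over 7092 genes. With 2 libraries per group the deviations mirror each other, so both replicate numbers give the same value. In these sums it shows no pairing by replicate number but cannot exclude one. It was not read within classes, where more genes were called with the block than without it in each class listed next. With the replicate number as a block, counts were 9 in dendritic cells, 11 in endothelial cells, 56 in ependymal cells, 4 in microglia, 3 in macrophages, 554 in neurons, 74 in pericytes, 147 in Spp1-high myeloid cells and 347 in T cells, and the NK share change was 2.02 (adjusted p = 0.0746).

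Lists called with 1 library left out numbered 1 to 3 in dendritic cells, 1 to 5 in endothelial cells, 1 to 4 in ependymal cells, 5 to 11 in microglia, 2 to 8 in macrophages, 2 to 3 in neurons, 2 to 5 in pericytes, 8 to 12 in Spp1-high myeloid cells, 6 to 9 in T cells and 1 to 2 over all cells. The estimated correlation called 0 in each class, and fry 0 except for 1 in ependymal cells; Leiden resolution 2 called 3 in macrophages and T cells without a CD8 UMI 1. In those T cells the log2 fold change was -0.002 for Cd4, 0.15 for Trgc2, 0.34 for Trgv2, 0.20 for Nkg7, 0.21 for Gzmk, 0.11 for Ccl5, 0.09 for Havcr2 and -0.04 for the proliferation list, and in T cells with one it was -0.16 for Cd40lg. At Leiden resolution 2 macrophages had -0.26 for Cxcl13, 0.01 for Spp1, 0.03 for disease-associated and -0.03 for lipid genes. With 1 library left out, endothelial Cxcl10 ran from -3.07 to 0.64, activation from -0.81 to 0.09 and interferon-gamma genes from -0.59 to 0.03. Macrophage type I interferon genes ran from -0.60 to 0.08, pericyte stress genes from -0.32 to 0.05 and fibrotic genes from -0.42 to 0.29, and in T cells interferon-gamma genes from -0.55 to 0.06 and residence genes from -0.54 to 0.14.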

Other observations

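The tests of the T-cell clusters, of T cells with a CD8 UMI, of the neuron clusters and of both interferon explanations were chosen only after the results were seen, and that of T cells without a CD8 UMI after the data were seen but before its result. Among T cells, a Cd4 UMI was found in 3.26% and 10.7% of cells in IgG and 17.8% and 15.6% in anti-CD8, and in 0.865%, 0.797%, 0.749% and 1.04% of microglia. After thinning to 2000 UMIs the T-cell shares were 1.20%, 6.64%, 10.7% and 10.2%. A UMI of Trdc, the gamma-delta receptor constant gene, was found in 2.37% and 6.29% of T cells in IgG and 14.0% and 8.33% in anti-CD8 (thinned 1.80%, 5.93%, 13.5% and 7.42%).

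Some genes had the same sign in all 9 classes tested, chosen after their values were seen and with no test across classes. The mitochondrial genes mt-Atp6 (log2 fold change -0.87 to -0.49) and mt-Co3 (-0.71 to -0.38) and the Mediator kinase gene Cdk8 (-0.63 to -0.30) were below 0, and Tex14 (0.24 to 1.20) and Ell2 (0.11 to 1.02) above. The median mitochondrial share of UMIs in kept cells was 2.3% and 2.1% in IgG and 1.95% and 1.6% in anti-CD8. Over all cells, haemoglobin genes were highest in IgG replicate 1, with Hbb-bs at 1134 UMIs against 1, 37 and 44, and Hba-a1 at 347 against 1, 25 and 4. Of the sex-linked genes, Ddx3y was at 84.0, 80.4, 84.0 and 96.9 CPM and Xist at 0.106, 0.0284, 0.0503 and 0.0450 CPM in the order IgG 1, IgG 2, anti-CD8 1 and anti-CD8 2.

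The genes called in T cells were set against a different mix of cells. Here and below, 95% intervals of medians over genes treat genes as independent, which they are not. These intervals do not cover the spread between libraries. In T cells without a CD8 UMI the called genes kept a median of 0.17 of their log2 fold change (95% interval 0.13 to 0.23, 108 genes measured). A mix of cells with and without a CD8 UMI predicts such a low ratio. In T cells with a CD8 UMI the called genes kept 0.80 (0.68 to 0.90, 98 genes), where such a mix alone predicts a low ratio too. The genes were called in sums that include these cells, which can raise that ratio, so it cannot exclude such a mix as the whole cause. In the largest cluster alone the ratio was 0.79 (0.71 to 0.86, 99 genes), but that cluster held 1488 of the 1766 T cells and its own makeup differed, with a CD8 UMI in 89.3% and 75.5% of its cells in IgG and 47.5% and 42.3% in anti-CD8. For these called genes, a different mix of T-cell kinds therefore cannot be told apart from a change within them. The CD4 and cytotoxic lists, by contrast, lost their change in both parts of the split. A mix of cells with and without a CD8 UMI predicts that. A direct effect of the antibody group may remain and was not tested apart from the groups.

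The genes called higher in neurons moved with microglial RNA. The median log2 fold change of the 9 measured microglia markers in neurons was 0.89 (95% interval 0.63 to 1.26), against 1.21 for the genes called higher. RNA or doublets of microglia may therefore account for part of these. Endothelial markers had a median of 1.12 (7 of 8 measured above 0), at 60.43 and 154.0 CPM together in IgG and 341.6 and 205.6 in anti-CD8, without TMM. Endothelial RNA was not tested as a cause. Dilution by RNA of other cells did not account for the genes called lower, since neuron markers had a median of -0.06 (-0.28 to 0.19) against -1.30. In the largest cluster alone the ratio to the log2 fold change in all neurons was 0.92 (0.87 to 0.96, 85 genes). That cluster held 470 of the 540 neurons. At Leiden resolution 2 it split into parts of 48 and 32 cells and of 99 and 63 in the IgG libraries. In the anti-CD8 libraries the parts held 48 and 47 cells and 74 and 59. The shift between these parts was small, which argues against it as the source of changes like the medians of 1.21 and -1.30. A different mix of neurons inside these parts cannot be told apart from a change within the cells. An effect of the antibody group was not tested and stays open.

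The lower type I interferon list in microglia leaned on IgG replicate 1. Without that library the median log2 fold change was -0.07 (95% interval -0.15 to 0.03), against -1.27 with it, which argues against the antibody group as the source of a change of that size. Without the interferon cluster, which held 6.53%, 0.906%, 0.495% and 1.15% of cells, the median was -0.39 (-0.57 to -0.20), with 23 of 24 members below 0. That interval spans the bound of -0.25 set for this test, so cells of that cluster alone cannot be told apart from a wider change in that library. What set that library apart was not tested.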
